A study of Mus musculus with 6 samples.

How the data were processed

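ATAC-seq, which marks accessible DNA by the insertion of sequencing adapters with the Tn5 transposase, was measured in 6 samples of CGR8 mouse embryonic stem cells. Per the labels, the samples carried the names mito, LM and eG1-1, with 2 replicates each, and the cells grew untreated in a serum-free medium with N2 and B27 supplements, a GSK3 inhibitor, a MEK inhibitor and leukemia inhibitory factor. The series title names mitotic exit, so the 3 names were taken in the order mito, LM, eG1-1 and read as mitosis, late mitosis and early G1. The labels do not spell the names out, and the peak names of both LM lists read Telo in place of LM. The number of cells per sample is not settled either, since the titles and the protocol in the labels disagree. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

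Each sample had 1 deposited list of peaks with 5 columns: chromosome, start, end, name and a score. Per the labels' protocols, nuclei were treated with Tn5 made in the laboratory, and libraries were read as paired-end reads. The submitters' processing notes name STAR 2.7.0e, Picard, SAMtools 1.10, deepTools 3.5.1, MACS2 2.2.4 and bedtools, with the mouse builds mm10 and GRCm38, without giving their roles. The peak names in the deposited lists show that peaks were called per sample on paired-end fragments, so replicates were not pooled. Whether read ends were shifted for the Tn5 insertion offset, and the threshold of the caller, are not given in the sources used here.

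The score is the authors' own value for each peak. Scores in the deposited lists were whole numbers with a lowest value of 13 in every list, and what they were scaled to is not given. They were used only to rank, filter and describe peaks within a list. The lists hold no read counts, so the depth of each sample is unknown, and a missing peak means only that none was called. A more deeply read sample gives more peaks, so the planned trends, region counts, shares and Jaccard indices were also computed on the 20639 strongest peaks of each list, the length of the shortest list. The results on gene families outside the fixed lists, on chromosome 8, on the distal ratios of the other gene lists and on random gene lists were not. Wilson 95% intervals on shares of regions cover counting error only.

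The peak names also showed that all replicate 1 samples came from 1 sequencing run and all replicate 2 samples from another. Replicate number was therefore also a batch, shared by 3 samples per run. The pairing comes from these names and not from the values: deviations of same-numbered lists over the regions correlated at 0.0328 for mito and LM, 0.0141 for LM and eG1-1 and 0.0324 for mito and eG1-1.

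Peaks of the 6 lists were merged into regions where they overlapped by at least 1 bp. A region was counted in a group where both of its lists held a peak, and absent where neither did. Gene positions came from a RefSeq gene table on GRCm38.p6, the assembly of mm10, which gives the start and end of 21887 protein-coding genes without strand or exons. The promoter analysis planned around transcription start sites was therefore made around both annotated ends: a peak was called a gene-boundary peak when its centre lay within 1 kb of either end of a protein-coding gene, and distal otherwise. A gene had a boundary peak when any peak overlapped 1 kb either side of either end. Boundary peaks thus include peaks at 3′ ends and peaks of a neighbouring gene. Peaks at transcription start sites inside the annotated ends of a gene count as distal. A planned test of 13 sequence motifs was not run, because no genome sequence was used here.

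The tests, the gene lists and the rule for named genes were fixed before the data were examined. Each value per list was tested for a trend over the order mito, LM, eG1-1 by an exact two-sided permutation test of the least-squares slope over 90 assignments of the 6 lists, with a smallest p of 0.0222. With all 6 lists the LM values carry no weight in the slope, which rests on mito and eG1-1 alone. A slope therefore does not show that LM lay between them. A second test permuted only within each sequencing run, over 36 assignments with a smallest p of 0.0556. A comparison of 2 lists against 2 cannot go below an exact p of 0.333, so group differences are given with SDs and without a threshold. Similarity of lists was measured as the Jaccard index in bp and tested exactly over 15 ways to part the lists into pairs, with a smallest one-sided p of 0.0667. Benjamini-Hochberg adjustment was made over the 18 trends and over the 12 gene lists. The lists covered pluripotency, housekeeping, G1 and S phase, G2 and M phase, immediate early and stress genes, primed and germ layer genes, fibroblast and other cell types, two-cell-like genes, chromatin architecture, mitochondrial and metabolic genes, ribosomal proteins and replication-dependent histones. Of 254 symbols written out in them, 251 were found in the gene table. Ribosomal protein and histone genes were taken by symbol pattern.

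Named genes were Pou5f1, Sox2, Nanog, Klf4 and Esrrb, and, for each comparison, genes with a boundary peak in both lists of 1 group and in neither list of the other. At most 3 per gene list and direction were named, and 5 per direction over all protein-coding genes, by the score in the weaker of the lists that held the peak. For distal regions the number was 3 per direction. Not every gene that the rule selects is reported here.

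Alternatives were the run-wise permutation, leaving out each list in turn, a score of at least 50, equal list length, an overlap of 50% of the shorter peak, merging within 200 bp, boundary windows of 500 bp and 2.5 kb, and distal windows of 20 kb and 100 kb. Added after seeing the data were a gene-boundary share standardised to a common distribution of peak widths, alone and at equal list length. Counts of the 4 other ways to part the lists of a comparison into 2 and 2 were also added then. Of these, 2 set one sequencing run against the other and so carry any difference between runs, and 2 cross groups and runs, so that both are balanced. The code was tested on simulated data: all 200 regions planted in 20000 were recovered, and 80 other regions received the same call. Planted regions were exempt from the random loss of peaks, which was equal in all lists, so this checks the code and measures no sensitivity. Of 400 trend tests without an effect, 4% fell under 0.05. For 1 pair of the deposited lists, overlaps in bp and in peaks equalled those of bedtools 2.31.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.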

Results

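Chromatin accessibility was measured by ATAC-seq in CGR8 mouse embryonic stem cells at 3 points named mito, LM and eG1-1, with 2 lists of peaks per group. The question the series title poses is how the genome of pluripotent cells is reactivated as cells leave mitosis. The mito lists held 24598 and 30446 peaks, the LM lists 23867 and 20639, and the eG1-1 lists 32101 and 48396. Together they covered 65324 regions of the mouse genome (mm10), and 10114 regions had a peak in all 6 lists. The read depth of each list is unknown. The median peak was 456 and 503 bp wide in mito, 459 and 336 bp in LM, and 340 and 410 bp in eG1-1.

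As deposited, the eG1-1 lists held more distal peaks than each earlier list. Distal peaks numbered 30375 ± 9605 in eG1-1, 14042 ± 555 in LM and 17604 ± 3434 in mito (SD, n = 2 each). Peaks at the ends of protein-coding genes numbered 9874 ± 1918, 8212 ± 1728 and 9918 ± 701 in the same groups. The gene-boundary share was therefore 36.2% ± 2.90 in mito, 36.7% ± 4.00 in LM and 24.9% ± 2.36 in eG1-1 (SD, n = 2 each). Within the first sequencing run the shares were 38.3% in mito, 39.5% in LM and 26.5% in eG1-1, and within the other run 34.2%, 33.9% and 23.2%. Both eG1-1 lists thus lay below all 4 other lists, with a slope of −5.69 percentage points per step that did not pass the exact permutation test (p = 0.0889, two-sided). With the 20639 strongest peaks of each list the shares were 41.5% and 40.7% in mito, 42.5% and 33.9% in LM and 32.0% and 32.8% in eG1-1, so that LM replicate 2 lay near the eG1-1 lists. The number of peaks had a slope of 6363 per step (exact permutation p = 0.267), the covered length one of 1.23 Mb (exact p = 0.733) and the median width one of −52.3 bp (exact p = 0.178). Without eG1-1 replicate 2 the first 2 slopes were 1210 peaks (exact p = 0.733) and −1.86 Mb (exact p = 0.3), and at a score of at least 50 the number of peaks had a slope of 2726.

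Gene-boundary regions also ranked less high in eG1-1. Among the 10114 regions held by all lists, of which 4975 were at a gene boundary, the probability that a gene-boundary region had a higher score than a distal region was 0.666 ± 0.00732 in mito, 0.668 ± 0.0531 in LM and 0.593 ± 0.00137 in eG1-1 (SD, n = 2 each). The replicate 1 lists gave 0.671, 0.705 and 0.592 in that order, and the replicate 2 lists 0.661, 0.630 and 0.594. The slope was −0.0365 per step (exact permutation p = 0.133, two-sided).

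**Figure D1:**
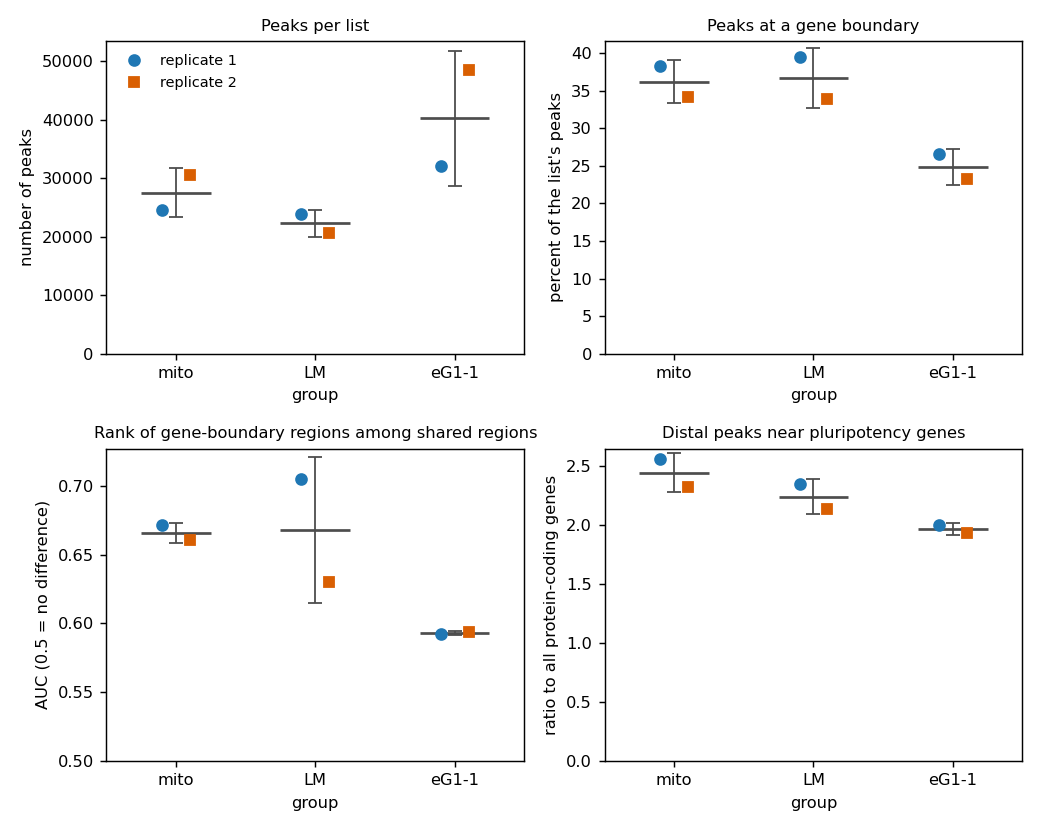
The 4 panels plot, for each group on the x axis, the number of peaks, the percent of peaks at a gene boundary, the AUC of gene-boundary against distal regions among the 10114 shared regions (axis from 0.5), and the ratio of distal peaks near pluripotency genes to that near all protein-coding genes. Points are the replicate 1 and replicate 2 lists, horizontal lines are means and error bars are SDs (n = 2); both eG1-1 lists lie lowest in every panel except the number of peaks, where they lie highest.

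The comparison of mito and eG1-1 asked which accessible sites differ between mitosis and early G1. Genes with a boundary peak in both mito lists and in neither eG1-1 list included Mycn (scores 50 and 65 in the mito lists), Dppa5a (68 and 47) and Sall4 (34 and 61), which are associated with the pluripotent state. Mcm2, a subunit of the replicative helicase, scored 78 and 96 in mito and 113 and 87 in LM, and Rrm2, a subunit of ribonucleotide reductase, 38 and 63 in mito. In all, 431 of 21887 protein-coding genes were held by both mito lists and neither eG1-1 list, and 352 the other way, while the 2 splits that cross groups and runs gave 204 and 83, and the 2 that set one sequencing run against the other gave 81 and 567. Chaf1a, the large subunit of the chromatin assembly factor CAF-1, was held by both eG1-1 lists (87 and 169) and by both LM lists (84 and 123) but by no mito list.

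Of the gene lists, pluripotency contributed 4 of 34 genes to the mito side, ribosomal proteins 6 of 80, histones 5 of 63, primed and germ layer genes 3 of 26 and G1 and S phase 2 of 28. The ribosomal protein genes included Rps27l (scores 102 and 152), Rpl9 (55 and 50) and Rpl12 (46 and 46), and the histone genes H2bc7 (64 and 76), H4c6 (60 and 51) and H4c4 (38 and 79). The primed and germ layer genes included Nes (34 and 35) and Lhx1 (37 and 28), which mark neural or mesodermal precursors. Cox4i1 (50 and 28) and Cox6c (82 and 43), both subunits of cytochrome c oxidase, were the members from the housekeeping and the mitochondrial lists. The other direction held 1 G1 and S phase gene, Chaf1a, and 1 ribosomal protein gene, Rpl39l (26 and 85). Over all protein-coding genes, the highest scores on the mito side were at Bicra (154 and 167), Lmtk2 (141 and 181), Rab5if (159 and 138), Rbbp7 (148 and 126) and the mechanically gated channel gene Piezo1 (124 and 142). On the eG1-1 side they were at Mospd1 (184 and 191), Lin37 (180 and 209), Tigd3 (147 and 138), Gstm2 (128 and 132) and Cd300lg (124 and 133). Lin37 encodes a subunit of the MuvB core, which regulates cell cycle genes.

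Regions held in mito and not in eG1-1 lay at gene boundaries more often than those held in eG1-1 and not in mito. Both eG1-1 lists and neither mito list held 5272 regions, of which 8.54% were at a gene boundary (Wilson 95% interval 7.81% to 9.32%). Both mito lists and neither eG1-1 list held 1210 regions, of which 40.6% were at a gene boundary (37.9% to 43.4%). Over all regions of both mito lists the share was 42.5%, and over those of both eG1-1 lists 30.9%. The mito regions without an eG1-1 peak were thus not richer in gene boundaries than mito regions as a whole. The eG1-1 regions without a mito peak were poorer in them than eG1-1 regions as a whole. With the 20639 strongest peaks of each list, the counts of such eG1-1 and mito regions became 2147 and 2372, and their gene-boundary shares 9.97% and 45.5%. Lists cut to equal length leave little room for a surplus on either side, whatever its source. These counts therefore do not show whether the surplus of eG1-1 regions came from depth. The crossed splits gave 1016 and 555 regions, and 557 and 571 at equal length, and the splits by run 421 and 3284, and 741 and 915 at equal length. Where 1 list stood for a group the counts grew, for eG1-1 and not mito to 8632 without mito replicate 2, 21402 without eG1-1 replicate 1 and 11155 without eG1-1 replicate 2. For mito and not eG1-1 they grew to 5100 without mito replicate 1, 3631 without mito replicate 2 and 4223 without eG1-1 replicate 2. For protein-coding genes at equal length, both mito lists and neither eG1-1 list held 1183 genes and the reverse 181, against 146 and 129 for the crossed splits and 175 and 196 for those by run. As deposited these group counts were 431 and 352. The cut took more peaks from the longer eG1-1 lists, which had the lower gene-boundary share. The large surplus of mito genes therefore depends on the cut.

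The distal regions named here were picked for the highest scores in each direction, so their height is no result in itself. On chromosome 13, from 112578184 to 112578726 within Il31ra, the mito lists scored 1102 and 1427 and LM replicate 1 scored 400, with no peak in LM replicate 2 or in eG1-1. Also on chromosome 13, the region from 9011708 to 9012167, which lies 15822 bp from Gtpbp4, scored 772 and 409 in mito and 315 and 607 in LM, with none in eG1-1. A region on chromosome 3 from 62159103 to 62159362, between genes, scored 330 and 610 in mito and 135 and 484 in LM. On chromosome 16, from 35981473 to 35982010 and 1546 bp from Kpna1, the eG1-1 lists scored 1446 and 845 and LM replicate 2 scored 2980, with no peak in mito or LM replicate 1. Between genes on chromosome 15, from 102673572 to 102674041 and 2760 bp from Atp5g2, the eG1-1 scores were 329 and 314.

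The comparison of LM and eG1-1 covered the step from late mitosis to early G1. The replication gene Mcm2 was held in both LM lists (scores 113 and 87) and in neither eG1-1 list, as were Lmtk2 (99 and 74), the tRNA exporter Xpot (91 and 73) and the neighbouring genes Ranbp1 and Trmt2a, which share 1 peak (75 and 70). Among ribosomal protein genes Rps10 was the 1 member on this side (45 and 35). In the other direction, both eG1-1 lists and neither LM list held Fgf4 (87 and 152) and Tdgf1 (71 and 57), which encode secreted or surface signalling proteins of stem cells, and Rpl26 (46 and 39) and Rpl39l (26 and 85). The highest scores on this side were at Bhmg1 (194 and 264), Oscar (152 and 162), Zc3hc1 (139 and 161) and the neighbouring genes Dctn2 and Kif5a, which share 1 peak (167 and 130). Most of these peaks were not new in eG1-1. Both mito lists also held Bhmg1 (40 and 116), Oscar (73 and 92) and Zc3hc1 (79 and 51). They likewise held Fgf4 (73 and 39), Tdgf1 (28 and 82) and Rpl26 (69 and 59). Dctn2 and Kif5a had a peak in mito replicate 1 (91), and Rpl39l had none in mito.

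Both eG1-1 lists and neither LM list held 514 protein-coding genes, and both LM lists and neither eG1-1 list held 105. For regions the counts were 6129, of which 9.95% were at a gene boundary (Wilson 95% interval 9.23% to 10.7%), and 300, of which 39.0% were (33.7% to 44.6%). Over all regions of both eG1-1 lists the share was 30.9%, and over those of both LM lists 44.7%. The crossed splits gave 939 and 31 genes and 2639 and 381 regions, and those by run 238 and 202 genes and 713 and 1775 regions. At a score of at least 50 the group counts of regions were 3699 and 129. At equal list length the counts of genes became 164 for eG1-1 and 585 for LM, against 106 to 406 for the 4 other splits, so the direction of the surplus turned, and those of regions 1637 and 1275, against 814 to 1126. Here too the cut took more peaks from the longer eG1-1 lists, so the turn does not show a loss at gene ends. For eG1-1 and not LM, 9843 regions were counted without LM replicate 1, 23756 without eG1-1 replicate 1 and 12227 without eG1-1 replicate 2. For LM and not eG1-1, 2145 and 3322 were counted without LM replicate 1 and 2, and 510 and 1683 without eG1-1 replicate 1 and 2. Among distal regions, one on chromosome 6 from 47748300 to 47748569 scored 287 and 317 in eG1-1 and 201 and 413 in mito, with no peak in LM. A region within Mast1 on chromosome 8, from 84944339 to 84944924, scored 193 and 185 in eG1-1 and 66 in mito replicate 1, with no peak in mito replicate 2 or LM.

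The comparison of mito and LM covered the step within mitosis. Of the pluripotency genes, 5 of 34 had a boundary peak in both mito lists and neither LM list, and 0 the other way. They included Lin28a (scores 60 and 67), an RNA-binding protein, Mycn (50 and 65) and Fgf4 (73 and 39). Ribosomal protein genes also contributed 5 of 80, among them Rpl26 (69 and 59), Rps27 (58 and 84) and Rpl9 (55 and 50), and histone genes 2 of 63, H4c4 (38 and 79) and H3c10 (66 and 27). Ccnd2 (42 and 42), a D-type cyclin, Fosb (57 and 50), an immediate early gene, and Lhx1 (37 and 28) were the members of their lists. Over all protein-coding genes the highest scores were at Gtpbp2 (314 and 246), the splicing regulator Rbfox2 (198 and 185), Tsga10 (170 and 180), Ermap (159 and 222) and Ackr3 (135 and 126). Each of these had a peak again in eG1-1. Rbfox2 (26 and 51) and Ackr3 (92 and 234) had it in both lists, Tsga10 (162) and Ermap (195) in replicate 1 and Gtpbp2 (236) in replicate 2. Fgf4 and Rpl26 also had peaks in both eG1-1 lists. Lin28a, Ccnd2, Fosb and Rps27 had a peak in a single eG1-1 list. Mycn, Lhx1, Rpl9, H4c4 and H3c10 had none there.

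In the other direction, both LM lists and neither mito list held Otulinl (95 and 111), Chaf1a (84 and 123), Lin37 (75 and 82), Scpep1 (74 and 91) and Katnal2 (66 and 57). In all, 474 protein-coding genes were held in mito and not in LM and 78 in LM and not in mito, but another way to part the same lists, mito replicate 2 with LM replicate 1 against the rest, gave 497. For regions the counts were 2327 and 591, against 442 and 1803 for the crossed splits and 1014 and 1449 for those by run. At equal length they were 1169 and 853, against 693 and 985 for the crossed splits and 1155 and 1096 for those by run, and at a score of at least 50 those in LM and not mito numbered 222. The genes at equal length numbered 333 and 165, against 101 to 492 for the 4 other splits. With 1 list left out, regions in mito and not LM numbered 8978 and 5692 without mito replicate 1 and 2 and 6173 and 3837 without LM replicate 1 and 2, and those in LM and not mito 993, 1772, 3935 and 4035 in the same order. Distal regions held in LM and not in mito included those on chromosome 13 from 66311911 to 66312451 (105 and 212) and on chromosome 11 from 23124410 to 23124912 (95 and 129). A region within Ky on chromosome 9, from 102544715 to 102545244, scored 122 and 111 in mito and had no peak in LM.

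Gene groups were then followed over all 3 points. Of the G2 and M phase list, which holds regulators of mitosis such as Ccnb1 and Plk1, all 27 genes had a boundary peak in both mito lists and 25 in all 6 lists. Pluripotency genes with a boundary peak made up 75.0% ± 2.08 in mito, 45.6% ± 14.6 in LM and 51.5% ± 18.7 in eG1-1 (SD, n = 2 each). Ribosomal protein genes stood at 83.1% ± 6.19, 61.3% ± 19.5 and 66.3% ± 10.6, and replication-dependent histone genes at 77.8% ± 2.25, 55.6% ± 20.2 and 62.7% ± 7.86. Over all protein-coding genes the shares were 48.5% ± 2.74, 41.6% ± 8.26 and 47.4% ± 7.50. Among the 6 lists of peaks, LM replicate 2 held the lowest share, or one level with it, in 10 of the 12 gene lists, with 35.3% of pluripotency and 47.5% of ribosomal protein genes, while LM replicate 1 held 55.9% and 75.0%. Its share over all protein-coding genes was also the lowest, 35.7% against 47.4% in LM replicate 1, so this count in part restates a lower share over the whole genome.

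Relative to all protein-coding genes of the same list of peaks, 10 of the 12 gene lists had a negative slope from mito to eG1-1, and 0 passed the exact permutation test, adjusted over the list alone or not (smallest p = 0.0889, smallest adjusted p = 0.373). The slopes in percentage points per step were −11.2 for pluripotency (exact p = 0.111), −7.89 for ribosomal proteins (exact p = 0.111), −7.14 for housekeeping genes (exact p = 0.0889) and −6.99 for histones (exact p = 0.133). With other settings, pluripotency had a p under 0.05 with a 500 bp window (−5.66, exact p = 0.0444) and ribosomal proteins at equal list length (−11.1, exact p = 0.0444), while the pluripotency slope was −3.75 at a score of at least 50 (exact p = 0.356). G1 and S phase genes and chromatin architecture genes had slopes of −4.81 each (exact p = 0.156 and 0.289), immediate early and stress genes −4.21 (exact p = 0.467), and primed and germ layer genes −3.30 (exact p = 0.311). Mitochondrial and metabolic genes (−1.53, exact p = 0.533) and G2 and M phase genes (−1.30, exact p = 0.556) had the flattest slopes, but the G2 and M phase list stood at 100% in 4 of the 6 lists and at 92.6% in the others, so its slope could show little of a change. Single lists moved several slopes. Without mito replicate 1, immediate early and stress genes had −0.551, histones −4.29 and fibroblast and other cell types 1.36. Without eG1-1 replicate 1, chromatin architecture had −2.09 and mitochondrial and metabolic genes −0.513. Without eG1-1 replicate 2, primed and germ layer genes had −2.04 and immediate early and stress genes −6.81. The latter had −9.32 at a score of at least 50 and −12.4 at equal list length (exact p = 0.178 and 0.111). The G1 and S phase slope was −0.388 at a score of at least 50, −2.02 at equal list length and −1.72 with a 500 bp window, where that of chromatin architecture turned to 0.0700. The slope of primed and germ layer genes turned to 2.36 at a score of at least 50 and to 2.31 at equal list length. Markers of fibroblasts and other cell types had a slope of 3.68 (exact p = 0.333), with 18.8% ± 8.84 of 24 genes held in mito and 25.0% in both eG1-1 lists. Two-cell-like genes had a slope of 2.47 (exact p = 0.400), with 0% of 13 genes in every list of peaks except eG1-1 replicate 2, at 7.69%. Their mean share thus went from 0% in mito to 3.85% in eG1-1, and the subtracted share over all protein-coding genes from 48.5% to 47.4%. More of this slope therefore came from eG1-1 replicate 2 than from the subtraction. Without eG1-1 replicate 2 the slope was 3.73 and came from the subtraction alone, and without mito replicate 2 it was 1.01.

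**Figure D2:**
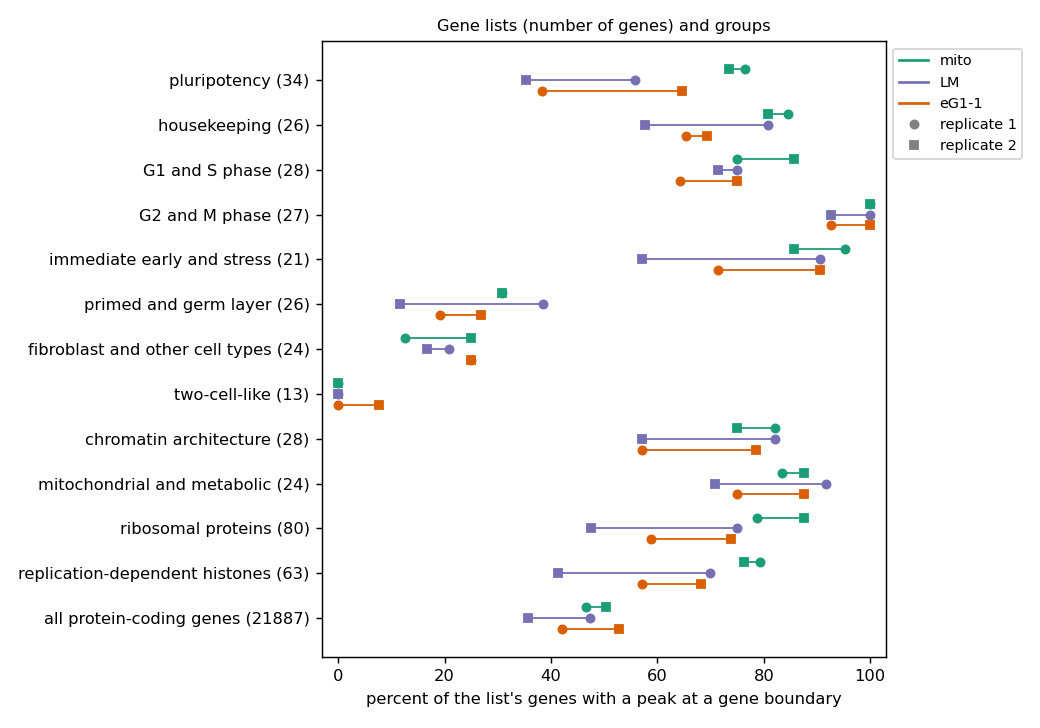
The plot gives the percent of genes with a peak at a gene boundary (x axis) for each of the 12 gene lists and for all 21887 protein-coding genes (y axis, number of genes in parentheses). Colours are the groups, circles and squares the replicate 1 and replicate 2 lists, and lines join the replicates of a group; pluripotency genes lie at 76.5% and 73.5% in mito and 55.9% and 35.3% in LM.

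The pluripotency factors themselves were read at their boundaries and at nearby distal regions. Pou5f1, which encodes OCT4 (NCBI gene 18999, chromosome 17, 35506032 to 35510777), had a boundary peak in both mito lists (scores 48 and 75), in LM replicate 1 (49) and in eG1-1 replicate 2 (43). Klf4 (gene 16600, chromosome 4, 55527137 to 55532475) had one in the same 4 lists, with scores of 24 and 58 in mito, 55 in LM and 40 in eG1-1. Sox2 (gene 20674, chromosome 3, 34649995 to 34652461) had a boundary peak in mito replicate 1 (50, from 34649854 to 34650109). LM replicate 2 had one at a separate site (24, from 34649129 to 34649324). Nanog (gene 71950, chromosome 6, 122707489 to 122714633) had one in mito replicate 1 (28, from 122715329 to 122715651). In eG1-1 replicate 2 it had one at the opposite end of the gene (46, from 122707273 to 122707582). Esrrb (gene 26380, chromosome 12, 86361117 to 86521628) had none at its annotated ends in any list. Start sites inside the gene were not read as boundaries, so this does not show that its promoters lacked peaks. Distal regions were read within 50 kb of either end, which leaves out the middle of Esrrb.

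Some distal regions near these genes were held throughout. A region 4772 bp from Nanog, on chromosome 6 from 122702301 to 122703133, had a peak in all 6 lists, with scores of 126 and 119 in mito, 82 and 57 in LM and 87 and 74 in eG1-1. A region 11976 bp from Klf4, on chromosome 4 from 55514716 to 55515605, also had one in all 6 lists (80 and 83, 83 and 35, 110 and 141). Near Sox2, the region on chromosome 3 from 34668359 to 34668845 was missing only from LM replicate 1, and near Pou5f1 the region on chromosome 17 from 35490264 to 35490998 likewise. Within Esrrb, the regions on chromosome 12 from 86501704 to 86502312 and from 86504088 to 86504629 had peaks in both mito lists and LM replicate 1, and none in LM replicate 2 or eG1-1.

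The density of distal peaks within 50 kb of pluripotency genes, relative to all protein-coding genes, fell from mito to eG1-1 by the trend test before adjustment, and not after it. The ratio was 2.44 ± 0.168 in mito, 2.24 ± 0.147 in LM and 1.96 ± 0.0483 in eG1-1 (SD, n = 2 each), with a slope of −0.240 per step (exact permutation p = 0.0444, two-sided; adjusted p = 0.343 over 18 trends). The replicate 1 lists gave 2.56, 2.34 and 2.00 and the replicate 2 lists 2.32, 2.13 and 1.93, so all 3 groups kept this order in both runs. With replicate as a block the exact p was 0.0556, the smallest that 36 assignments can give. The ratio sets 2 counts against each other: the distal peaks per pluripotency gene numbered 3.75 ± 0.478 in mito, 2.68 ± 0.333 in LM and 4.90 ± 1.48 in eG1-1, and those near all protein-coding genes 1.55 ± 0.302, 1.19 ± 0.0704 and 2.51 ± 0.815. Among all 12 lists, a comparison added after seeing the data, histones had a steeper slope (−0.304, exact p = 0.111), G2 and M phase genes had −0.0540 (exact p = 0.0222), and the other 9 lists lay between −0.129 and 0.0264 (exact p of 0.0889 or more). At equal list length the slope was steeper, at −0.3675 (exact p = 0.0222). The call also held with a 500 bp boundary window and with distal windows of 20 kb and 100 kb (exact p = 0.0222 each). It did not hold with only peaks of a score of at least 50 (exact p = 0.222) or a boundary window of 2.5 kb (exact p = 0.0667). Without mito replicate 1, eG1-1 replicate 1 or eG1-1 replicate 2 it did not hold either, with slopes of −0.194, −0.2495 and −0.220. Without mito replicate 2 the slope was −0.296. Without an LM list the slope was unchanged and the smallest p that can be reached is 0.0667.

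The early G1 regions were then looked up in the earlier lists. Of the 24110 regions held by both eG1-1 lists, 68.4% ± 5.85 had a peak in the mito lists and 61.2% ± 2.84 in the LM lists (SD, n = 2 each). At gene boundaries the shares were 88.5% ± 3.40 in mito and 81.3% ± 8.39 in LM, and at distal regions 59.4% ± 6.94 and 52.2% ± 0.365. Distal regions of early G1 were thus held less often than gene-boundary regions in each of the 4 lists. The difference of LM minus mito was −7.18 percentage points over all regions, and 0.501 at equal list length, where the direction turned. It was −3.03 without mito replicate 2 and −11.3 without mito replicate 1. At distal regions these values were −2.24 and −12.1, and at gene boundaries it was −1.24 without LM replicate 2 and −12.9 without LM replicate 1. At equal list length it was 2.11 at distal regions and −2.06 at gene boundaries, so only distal regions turned.

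**Figure D3:**
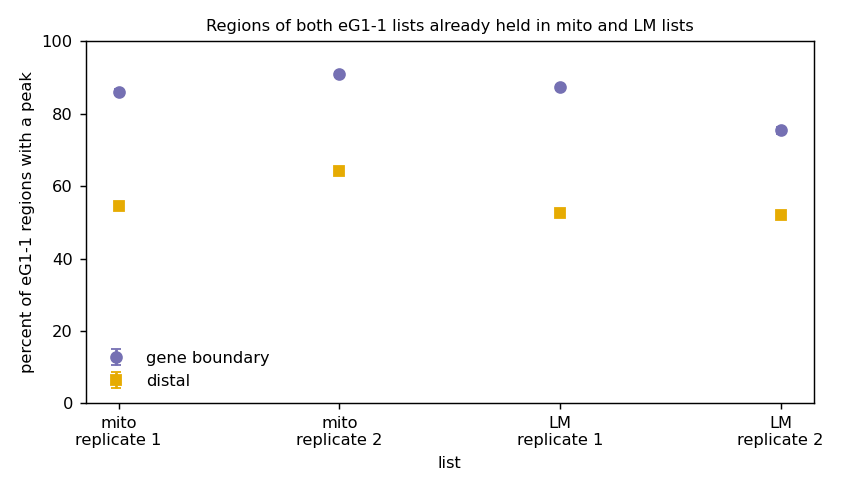
The plot gives the percent (y axis) of the regions of both eG1-1 lists that had a peak in each mito and LM list (x axis), for 7439 gene-boundary regions (circles) and 16671 distal regions (squares). Error bars are Wilson 95% intervals for counting error; gene-boundary regions lie between 75.4% and 90.9%, distal regions between 52.0% and 64.3%.

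Whole lists were compared by the bases they share. The Jaccard index averaged 0.359 over the 3 same-group pairs and 0.331 over the 12 other pairs, a difference of 0.0285 (exact permutation p = 0.133, one-sided). The mito lists had an index of 0.429 with each other, the LM lists 0.315 and the eG1-1 lists 0.335. The highest index of any other pair, 0.430, was between mito replicate 1 and LM replicate 1, level with that of the mito pair. The difference was −0.000229 without mito replicate 1, 0.00283 without mito replicate 2 and 0.0673 without LM replicate 1.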

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

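The alternatives were planned, except the width-standardised shares, which were chosen after seeing the data. Of 339 alternative values for 32 results, 277 kept their direction and side of the threshold, or their size. Part of these were fixed in advance. No trend can pass with replicate as a block or without an LM list, where most slopes stay as they were. The Jaccard test can pass in no setting. The count is therefore no measure of how robust the results are. Causes of the changes in the remaining values were not tested except where the construction shows them. The motif test was not run, and 50% overlap or merging within 200 bp moved no count by over 1.5 times. Depth is unknown and limits every count of missing peaks.

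The slope of the distal ratio near pluripotency genes stayed negative in all 13 alternatives, from −0.476 to −0.170. Its call held at equal list length (−0.3675, exact p = 0.0222), with a 500 bp boundary window and with distal windows of 20 kb and 100 kb (exact p = 0.0222 each). It was lost at a score of at least 50 (−0.259, exact p = 0.222) and with a 2.5 kb window (−0.194, exact p = 0.0667). Without mito replicate 1, eG1-1 replicate 1 or eG1-1 replicate 2 it was also lost. Slopes with 1 list left out lay between −0.296 and −0.194. With replicate as a block (−0.240, exact p = 0.0556) and without an LM list no trend can pass, since the smallest p is 0.0556 and 0.0667, so these settings decide nothing. The gene-boundary share had slopes of −7.45 to −3.49 and exact p of 0.0667 to 0.267 in 13 alternatives, −3.94 when width-standardised. The pluripotency list had slopes of −16.2 to −3.75: it passed with a 500 bp window (−5.66, exact p = 0.0444) and was weakest at a score of at least 50 (−3.75, exact p = 0.356). Ribosomal proteins passed at equal list length (−11.1, exact p = 0.0444), with slopes of −11.1 to −5.06 overall. The slope of the number of peaks lay between 1210 and 9278, and was 2726 at a score of at least 50.

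At a score of at least 50, regions numbered 11167 in mito, 6955 in LM, 13253 in eG1-1, 5271 in all groups and 2840 in eG1-1 and not mito, and the slope of primed and germ layer genes turned to 2.36. At equal list length there were 13979 regions in eG1-1, 2147 in eG1-1 and not mito and 2372 in mito and not eG1-1. LM minus mito of the early G1 regions held became 0.501, against −11.3 to −3.03 with 1 list left out, and slopes turned to −1.0 Mb for covered length, 1.45 for G2 and M phase and 2.31 for primed and germ layer genes. With a 500 bp window they turned to 0.0370 for G2 and M phase, 0.0700 for chromatin architecture and 0.963 for mitochondrial and metabolic genes.

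Leaving out 1 list gave covered-length slopes of −1.86 to 3.14, G2 and M phase slopes of −2.78 to 0.0301 and Jaccard differences of −0.000229 to 0.0673. A group with 1 list left counts every region of that list: 24117 to 30003 regions in mito, 20171 to 23503 in LM and 31426 to 47516 in eG1-1, and, with 1 list left in either group, 6646 to 21402 in eG1-1 and not mito and 1777 to 5100 in mito and not eG1-1. Where the list left out belonged to no group counted, the lowest counts were 18871, 13390, 24074, 5275 and 1214 in the same order.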

Other observations

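All tests in this part were chosen after the results were seen.

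Gene families outside the fixed lists were read as well. Transfer RNA genes, 408 in all, had a peak within 200 bp in 49.5% and 39.0% of cases in mito, 44.6% and 32.4% in LM and 35.8% and 41.4% in eG1-1 (exact permutation p for the trend = 0.467). Of 11 genes for SR splicing factors (Srsf), 90.9% had a boundary peak in both mito lists and in LM replicate 1, but 36.4% in LM replicate 2 and eG1-1 replicate 1, and 81.8% in eG1-1 replicate 2 (exact p = 0.267). Hox genes, which pattern the body axis, stood at 28.2% and 38.5% of 39 genes in mito, 33.3% and 7.69% in LM and 12.8% and 30.8% in eG1-1 (exact p = 0.444). Proteasome genes (Psm) lay between 70.0% and 92.5% of 40 genes in the 6 lists, zinc finger genes (Zfp) between 60.0% and 78.5% of 400, and olfactory receptor genes (Olfr) between 0.270% and 0.991% of 1110.

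LM replicate 2 stood apart from LM replicate 1: as deposited, it held 19.2% against 45.5% of the regions of both mito lists and no eG1-1 list, 20.1% against 16.7% of the regions of both eG1-1 lists and no mito list, and its median peak was 336 bp wide against 459 bp. Fewer peaks in the list account for only part of the difference at the mito regions. With LM replicate 1 reduced to as many peaks, its share there fell from 45.5% to 38.8%, and the difference was still −19.7 percentage points. At the eG1-1 regions the shorter list held 3.49 points more as deposited, which fewer peaks alone would not give. The sequencing run alone would not narrow the peaks, since in both other groups, mito and eG1-1 (2 of 2), the replicate 2 list had the wider peaks. A library type shared with eG1-1 replicate 1 stays open: the median width of 340 bp and the Srsf share of that list are close, the Jaccard index of LM replicate 2 was 0.314 with it and 0.263 with eG1-1 replicate 2 as deposited, but at equal length the second was the higher (0.347 and 0.358), as in all earlier lists, and the difference lay only 0.0148 above that of the next list, less than the range of the other 3. Chromatin closer to early G1 in LM replicate 2 may also contribute, since of the regions in eG1-1 replicate 2 but in no mito list and not in eG1-1 replicate 1 it held 8.06 points more than LM replicate 1 at equal length, but as deposited the shares were 6.58% against 5.73%, and for regions of eG1-1 replicate 1 alone 4.55% against 5.14% as deposited and 13.5% against 11.3% at equal length; unknown depth and library quality stay open too.

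Chromosome 8 carried a boundary peak at more of its protein-coding genes than any other chromosome in all 6 lists, for example at 62.2% in mito replicate 1, where other autosomes reached at most 54.9%, and at 68.2% in eG1-1 replicate 2 against 61.1%. Gene content remains open: without olfactory, vomeronasal and other large gene families, chromosome 8 still ranked highest in 6 of 6 lists, at 67.9% in mito replicate 1, but genes used in all cells were not separated. Extra copies of chromosome 8, which would raise all its regions, may account for part of it: its regions held by all lists had median scores of 1.07 to 1.20 times those of the other autosomes, highest of all chromosomes in 4 of 6 lists, and 6 of its 7 bins of 20 Mb lay above the autosome median, 3 of them in all lists, against 7 of 10 on chromosome 1 and 5 of 8 on chromosome 7. These values cannot tell the explanations apart, because scores depend on the kind of region as well as on copy number and no read counts were used. No biological explanation tied to the groups was tested.

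The lower ratio of distal peaks near pluripotency genes in eG1-1 may be a change shared by other genes rich in distal peaks. Among 10000 random lists of genes matched on the mean number of distal peaks, the slope of −0.240 lay at percentile 7.29, within the central 95% of the random slopes, from −0.276 to −0.00126, and the median random slope was −0.137. Lists of matched genes thus mostly had negative slopes too. A change at early G1 that concerns pluripotency genes beyond such genes was not shown, and the stage itself stays open as a biological explanation.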
